A study of Mus musculus with 12 samples.

How the data were processed

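RNA from 12 whole-brain samples was sequenced with a bulk variant of MARS-seq, a 3' tag method, per the labels' protocols. The deposited raw counts per gene symbol were whole numbers that had not been normalized. Per the submitters' processing notes, cutadapt, HISAT 0.1.6, HTSeq and DESeq2 were used with the mouse build mm10, and the notes give neither the role nor the order of these tools. How molecular identifiers were handled, which annotation and filters were used and whether counting used the strand is not given in the sources used here. The deposited normalized signal equalled the raw count multiplied by 1 constant per library, with a largest relative departure of 6.58e-10, and was used for that comparison alone. The authors' deposited table of comparisons holds a log2 fold change and a p-value with its adjusted form per gene, and was used only to count the genes it calls and those called in both.

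The count table held 16505 entries. In 23 of them, with 21 distinct names, a date stood in place of a gene symbol; they took 0.266% to 0.347% of the counts of a library and were left out of library sizes and of the tests, which left 16482 genes, 5 of them with no count. Genes were kept with filterByExpr (minimum count 10, minimum total 15), and 12623 were tested. Total counts ran from 1758446 to 6521257 per sample, and 15278 to 16152 genes had a count. Lower totals widen the error of low genes, and the 2 day 34 CBE samples had the lowest totals. Counting intervals were computed on counts pooled over the samples of a group, so they leave out the spread between samples. They may not cover counting error in full either, since molecular identifiers may not have been used to count molecules.

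Samples were grouped by the treatment in the labels into PBS, CBE and CBE+GZ-667161, with 4 samples each. Counts were scaled with TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in one fit of the 3 groups, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. The CBE samples of day 40 and day 34 were compared in a fit with 4 groups. Fold changes are log2 values with standard errors, and levels are counts scaled to TMM library size (CPM, as edgeR computes it) as mean and SD. For the plots and the principal components a prior count of 2 was used. Genes with at most 3 counts over the PBS samples are given as a ratio of counts with a 95% interval. Of 42 gene lists, 37 had at least 5 tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and with fry beside it. Some lists share members, so their results are not independent of each other. Cxcl10, for example, is in the interferon-stimulated, the chemokine and cytokine and the reactive astrocyte lists.

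Genes were named by a rule. It took the 8 largest rises and 8 largest falls among genes that passed with no overlap between the 4 and 4 samples. For each list that camera called, it took up to 4 passing members with the smallest p, or the 2 members of highest expression where none passed, and it took 12 genes fixed in advance whether or not they passed. Between the days it took the 3 largest rises and 3 largest falls. Some genes that the rule took are not reported here. The groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. Further alternatives, chosen after seeing the data, left out the day 40 CBE samples, used a weighted slope, used Xist as a covariate for the lists and for the count of genes in opposite directions, and estimated the correlation within lists under other alternatives.

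The share of the CBE effect remaining was a slope through the origin, with 200 genes chosen on 2 PBS and 2 CBE libraries and the slope taken on the rest, in each of 36 ways. Comparisons that share libraries were set beside 20 simulations and beside splits of the shared libraries. Alternatives were other scaling factors and filters, DESeq2 1.42.0, limma-voom, glmTreat against a fold change of 1.2, an adjusted p under 0.01, fits of fewer samples, age, Xist and replicate number as terms, and leaving out each library. The steps were tested on simulated data with 12423, 12401 and 12428 genes for CBE against PBS, CBE+GZ-667161 against PBS and CBE+GZ-667161 against CBE. Of genes simulated to change 1.5-fold, 17.9%, 19.4% and 19.4% were called, of those at 2-fold 61.2%, 58.2% and 65.7%, and of those at 4-fold 87.9%, 90.9% and 95.5%. Of 121, 129 and 133 calls, 6, 12 and 6 were false, which for CBE+GZ-667161 against PBS is more than the threshold of 0.05 implies. A share of 0.7 simulated in 400 of 12623 genes was estimated as 0.696. Gene positions are from GENCODE for mm10, matched by symbol for 129 of 130 named genes. Analyses ran in R 4.3.3 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.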

Results

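Whole-brain homogenates of C57BL/6 mice were profiled in 12 samples with a bulk form of MARS-seq, which counts tags from the 3' end of transcripts. Conduritol B epoxide (CBE) is given to mice to model neuronopathic Gaucher disease, in which glucosylceramide builds up. GZ-667161 is a brain-penetrant inhibitor of glucosylceramide synthase, the enzyme encoded by Ugcg that makes this lipid. The labels give 3 groups of 4 samples, namely vehicle (PBS), CBE, and CBE together with GZ-667161. All PBS and CBE+GZ-667161 samples were of postnatal day 40, whereas the CBE group held 2 samples of day 34 (replicates 2 and 3) and 2 of day 40 (replicates 4 and 6). The total count was 3883771, 4729240, 2423380 and 6521257 in PBS replicates 2, 3, 4 and 5. It was 1841257 and 1758446 in CBE replicates 2 and 3, and 3003757 and 3051435 in CBE replicates 4 and 6. In CBE+GZ-667161 replicates 2, 3, 4 and 5 it was 4338163, 4637622, 4917330 and 2217976.

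Of 16482 genes with a usable symbol, 12623 had enough counts to be tested. Replicates differed well beyond counting noise, with a chi-square per degree of freedom of 3.53 to 13.3 between samples of one group. The biological coefficient of variation was 0.193. The labels do not state that each sample came from a separate mouse, so p-values measure the spread between these samples, which may in part be technical. Xist, a transcript of the inactive X chromosome, lay at 7.96 to 25.7 CPM (counts scaled to library size) in PBS replicates 4 and 5 and CBE+GZ-667161 replicates 2, 3 and 5, with at most 1 count from Y-linked genes in each. The other 7 samples, among them all 4 CBE samples, had at most 0.555 CPM of Xist and 24 to 84 Y-linked counts. The sexes were thus not balanced between the groups. Ttr, a marker of the choroid plexus, ranged from 11.3 CPM in PBS replicate 4 to 517 CPM in CBE replicate 4. The first principal component, with 30.4% of the variance, ordered PBS, CBE+GZ-667161 and CBE samples. The second, with 13.9%, set the 2 day 40 CBE samples apart from the other 10.

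**Figure D1:**
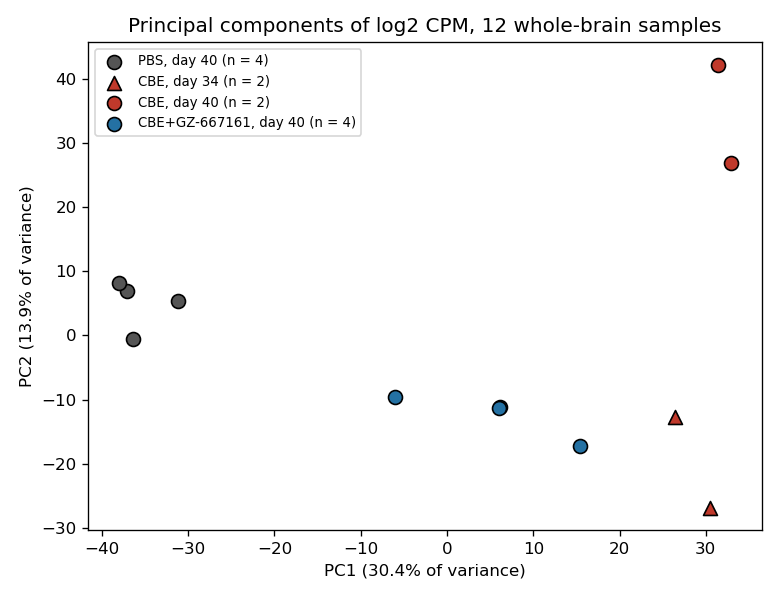
Principal components of log2 CPM over the 12623 tested genes, 1 point per sample, with PC1 (30.4% of variance) on the horizontal and PC2 (13.9%) on the vertical axis. Colours give the 3 groups of 4 and triangles the 2 CBE samples of day 34; the CBE+GZ-667161 samples lie between the PBS and the CBE samples on PC1.

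The comparison of CBE with PBS asked which transcripts accompany CBE treatment. Genes of activated microglia rose. Cst7, which encodes a cysteine protease inhibitor of activated microglia (mm10 chromosome 2, 150570415 to 150578944), went from 2.32 ± 1.02 to 128 ± 68.2 CPM (mean ± SD, n = 4 and 4), a log2 fold change of 5.90 ± 0.48 (SE; edgeR adjusted p = 3.7e-07). Lgals3, which encodes galectin-3, rose by 6.34 ± 0.45 (adjusted p = 1.3e-07), the chemokine gene Ccl3 by 5.60 ± 0.39 (adjusted p = 1.3e-07) and Spp1, which encodes osteopontin, by 4.41 ± 0.29 (adjusted p = 1.0e-07). Of the 30 genes of the disease-associated microglia list 29 rose, with a median log2 fold change of 2.46 (camera, adjusted p = 0.00044 with an estimated correlation). Adjusted over the list alone, 29 also passed. Clec7a, a receptor gene with 2 counts in all PBS samples together, was 158 times as abundant in CBE (95% counting interval 43.0 to 1312). Lilr4b and Cd300lf, also with 2 PBS counts, were 85.6 (23.1 to 718) and 73.8 (19.8 to 620) times as abundant.

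Genes induced by interferon rose as a group. Of 39 tested interferon-stimulated genes 38 rose, and 39 when adjusted over the list alone, with a median log2 fold change of 2.87 (adjusted p = 0.0081 with an estimated correlation). Irf7, an interferon regulatory factor gene, rose by 4.06 ± 0.29 (adjusted p = 1.3e-07). Cxcl10, an interferon-induced chemokine gene (chromosome 5, 92346638 to 92348889), rose from 7.91 ± 1.64 to 177 ± 92.1 CPM (log2 fold change 4.45 ± 0.36, adjusted p = 3.1e-07). Of 14 tested chemokine and cytokine genes 11 rose, among them Ccl5 by 4.76 ± 0.28 (adjusted p = 7.1e-08). In it 2 fell, Cxcl12 (-0.46 ± 0.13, adjusted p = 0.032) and Cx3cl1 (-0.51 ± 0.13, adjusted p = 0.016), both named after their values were seen. The counts adjusted over the list alone were 11 and 2. The median of this list was 3.72 (adjusted p = 0.0058 with an estimated correlation). Complement genes rose in 10 of 11 cases, and in 10 adjusted over the list alone (median 2.37, adjusted p = 0.0026 with an estimated correlation). They included C3 at 4.72 ± 0.39 (adjusted p = 3.7e-07), C4b at 3.42 ± 0.27 (adjusted p = 2.6e-07) and C1qb at 2.26 ± 0.17 (adjusted p = 1.5e-07). Of 18 antigen presentation genes 14 rose, and 15 adjusted over the list alone (median 2.07, adjusted p = 0.0081 with an estimated correlation). H2-K1, H2-D1 and B2m rose by 2.76 ± 0.19, 2.56 ± 0.16 and 2.46 ± 0.20 (adjusted p = 1.3e-07, 7.1e-08 and 3.8e-07). In the list of necroptosis, pyroptosis and apoptosis 6 of 12 genes rose, and 7 adjusted over the list alone (median 0.85, adjusted p = 0.022 with an estimated correlation). Zbp1, a nucleic acid sensor gene, rose by 4.50 ± 0.46 and Gsdmd, which encodes gasdermin D, by 1.32 ± 0.26 (adjusted p = 4.1e-06 and 0.0031). Zbp1 is also in the interferon-stimulated list. Ripk3, a kinase gene of necroptosis, had too few counts to be tested, with 7, 4 and 21 in all PBS, CBE and CBE+GZ-667161 samples.

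Reactive astrocyte genes rose in 23 of 28 cases, and in 23 adjusted over the list alone (median 2.48, adjusted p = 0.00037 with an estimated correlation). Gfap, the astrocyte intermediate filament gene (chromosome 11, 102887336 to 102900912), went from 81.0 ± 22.1 to 791 ± 209 CPM (log2 fold change 3.28 ± 0.27, adjusted p = 3.9e-07). Serpina3n, a protease inhibitor gene (chromosome 12, 104406729 to 104414329), went from 28.8 ± 12 to 788 ± 218 CPM (4.76 ± 0.34, adjusted p = 1.4e-07). Vim rose by 2.86 ± 0.22 (adjusted p = 2.0e-07) and Lcn2, which encodes lipocalin-2, by 5.99 ± 0.66 (adjusted p = 9.8e-06). The metallothionein genes Mt2 and Mt1, whose products bind metals, rose by 2.05 ± 0.18 and 1.62 ± 0.21 (adjusted p = 5.2e-07 and 5.0e-05). Hmox1, which encodes heme oxygenase-1, rose by 2.05 ± 0.28 (adjusted p = 8.9e-05). They belong to a list of 12 antioxidant and metallothionein genes of which 5 rose, also when adjusted over the list alone (median 0.23, adjusted p = 0.0097 with an estimated correlation).

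Lysosomal genes rose in 28 of 53 cases and fell in 1, Ids (-0.45 ± 0.13, adjusted p = 0.033, named after its value was seen). Adjusted over the list alone they were 29 and 1 (median 0.63, adjusted p = 0.0060 with an estimated correlation). Ctss and Cd68, genes of a protease and a membrane protein abundant in phagocytes, rose by 2.56 ± 0.16 and 3.0 ± 0.23 (adjusted p = 7.1e-08 and 1.9e-07). Cd68 and several cathepsin genes are also in the disease-associated microglia list. Ugcg (-0.27 ± 0.17, adjusted p = 0.35) and Gba2, which encodes the non-lysosomal β-glucosidase (-0.10 ± 0.13, adjusted p = 0.71), did not pass. Among 39 genes of sphingolipid metabolism 6 rose and 3 fell, also when adjusted over the list alone, with a median of 0.07, and the list did not pass (camera, adjusted p = 0.54). The 3 that fell were Ugt8a, Gal3st1 and Fa2h, genes of the synthesis of galactosylceramide and sulfatide in myelin. Of these Gal3st1 (-0.91 ± 0.23, adjusted p = 0.017) and Fa2h (-1.18 ± 0.31, adjusted p = 0.021) were named after their values were seen. Ugt8a (chromosome 3, 125865271 to 125938619) went from 11.2 ± 2.47 to 2.97 ± 2.27 CPM (-2.07 ± 0.45, adjusted p = 0.0061).

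Genes of cholesterol synthesis fell in 14 of 21 cases and rose in 0, with 16 falls adjusted over the list alone (median -0.80, adjusted p = 0.048 with an estimated correlation). Hmgcs1, which encodes an early enzyme of the pathway (chromosome 13, 119690379 to 119708260), went from 308 ± 39.5 to 146 ± 22.7 CPM (-1.08 ± 0.15, adjusted p = 0.00011). Srebf2, which encodes the transcription factor of this pathway, fell by 0.87 ± 0.17 on the log2 scale (adjusted p = 0.0025). In the list of cholesterol efflux and LXR targets 5 of 13 genes rose and 1 fell, Scd2 (-0.35 ± 0.11, adjusted p = 0.045, named after its value was seen). Adjusted over the list alone these were 5 and 3 (median 0.57, adjusted p = 0.040 with an estimated correlation). Apoe, the main lipid carrier gene of the brain, went from 4462 ± 372 to 10208 ± 629 CPM (1.19 ± 0.11, adjusted p = 9.3e-07). Ch25h, which encodes cholesterol 25-hydroxylase, rose by 3.09 ± 0.38 (adjusted p = 3.4e-05). Apoe and Ch25h are also in the disease-associated microglia list. The median of 13 mature oligodendrocyte genes lay at -0.58 beside these falls, with 2 falls, 4 adjusted over the list alone, and a list call that was lost with an estimated correlation (adjusted p = 0.29 with an estimated correlation).

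Pan-neuronal genes fell in 8 of 11 cases, and in 9 adjusted over the list alone (median -0.60, adjusted p = 0.0058 with an estimated correlation). The neurofilament genes Nefl and Nefm changed by -0.92 ± 0.13 and -0.86 ± 0.13 (adjusted p = 0.00011 and 0.00027). Of 29 synapse genes 9 passed with lower values, 12 adjusted over the list alone (median -0.37, adjusted p = 0.063 with an estimated correlation), with Homer1 at -1.13 ± 0.18 (adjusted p = 0.00050). Of 15 immediate early genes 6 were lower, also adjusted over the list alone (median -0.88, adjusted p = 0.29 with an estimated correlation), with Egr1 at -1.28 ± 0.29 (adjusted p = 0.0078). Levels are relative to all RNA of the brain. Whether these falls reflect fewer cells, dilution by RNA from other cells or a change within cells was not tested. Of 15 glucocorticoid-responsive genes 7 were higher, also adjusted over the list alone (median 0.67, adjusted p = 0.22 with an estimated correlation), with Fkbp5 and Sgk1 at 1.81 ± 0.37 and 1.02 ± 0.17 (adjusted p = 0.0042 and 0.00074). This list shares Fkbp5 and Lcn2 with the reactive astrocyte list. Camera with its preset correlation also called the lists of cell cycle (median 0.76), homeostatic microglia (0.78), astrocyte (0.29), ribosomal protein (0.21) and border macrophage and monocyte genes (1.26). Their adjusted p with an estimated correlation was 0.11, 0.29, 0.16, 0.39 and 0.072. The preset correlation also called excitatory neuron (-0.33), inhibitory neuron (-0.15) and erythroid genes (-0.76), with adjusted p = 0.30, 0.27 and 0.30 with an estimated correlation. Without the day 34 CBE samples the medians of homeostatic microglia and of border macrophage and monocyte genes were 0.0078 and 0.094, and neither list passed (adjusted p = 0.30 and 0.12). Without the day 40 CBE samples the glucocorticoid-responsive list did not pass (median 0.18, adjusted p = 0.071). No other list with at least 5 tested members passed.

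In total 1387 of 12623 genes passed at an adjusted p under 0.05 in this comparison, 877 higher and 510 lower in CBE, of which 568 and 91 differed by over 2-fold. In 1225 of them the 4 CBE and 4 PBS samples did not overlap, and such separation occurred in 15.6% of all tested genes against 2.86% by chance. The 8 largest falls that met the naming rule began with Apln (chromosome X, 48025146 to 48034853), which encodes the peptide apelin and went from 33.8 ± 5.81 to 7.15 ± 3.02 CPM (-2.30 ± 0.29, adjusted p = 4.6e-05). They ended with Adcyap1, the gene of the neuropeptide PACAP (-1.96 ± 0.33, adjusted p = 0.00077). With the day 34 CBE samples alone 751 genes passed, 652 higher and 99 lower, and with the day 40 samples alone 1798 passed, 1043 higher and 755 lower. The calls of Srebf2, Fkbp5, Egr1 and Ugt8a were among those lost without the day 40 samples. Of 125 named genes that passed, 100 kept the call whichever library was left out.

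**Figure D2:**
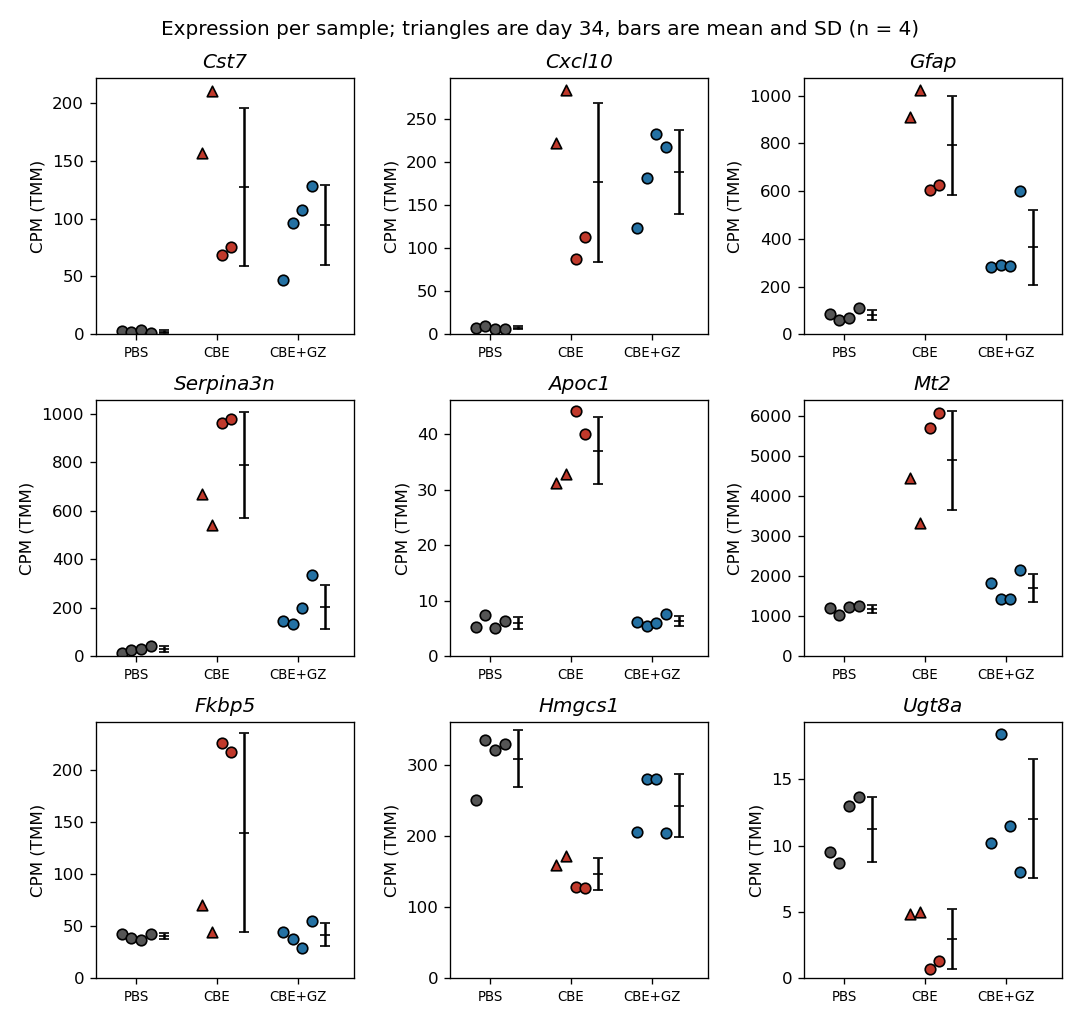
TMM-scaled CPM of 9 genes in each of the 12 samples, by group, with the mean and SD (n = 4) beside the points and triangles for the 2 CBE samples of day 34. Cst7 and Cxcl10 did not pass between CBE and CBE+GZ-667161 samples (adjusted p = 0.57 and 0.89), Apoc1 in CBE+GZ-667161 (6.30 ± 0.91 CPM) was near PBS (6.02 ± 1.10 CPM), and Gfap and Serpina3n lay between.

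Samples from mice given GZ-667161 with CBE were compared with PBS to ask what remained of the CBE profile under substrate reduction. Interferon-stimulated genes stayed high, with 37 of 39 above PBS, and 39 adjusted over the list alone (median 2.68, adjusted p = 0.0022 with an estimated correlation). Cxcl10 lay at 189 ± 48.8 CPM (log2 fold change 4.56 ± 0.36, adjusted p = 1.2e-06) and Irf7 at 148 ± 37.2 CPM (3.59 ± 0.28, adjusted p = 1.2e-06). Cst7 was at 94.4 ± 34.5 CPM (5.48 ± 0.48, adjusted p = 2.5e-06). In its list 23 of 30 disease-associated microglia genes rose, 28 adjusted over the list alone (median 1.77, adjusted p = 0.0011 with an estimated correlation). Gfap was at 365 ± 157 CPM (2.16 ± 0.26, adjusted p = 5.4e-05). With it 17 of 28 reactive astrocyte genes rose, with 17 higher and 1 lower adjusted over the list alone (median 1.51, adjusted p = 0.0013 with an estimated correlation). Clec7a was 69.8 times as abundant as in PBS (95% counting interval 18.9 to 583) and Cxcl13, with 3 counts in PBS, 46.2 times (15.5 to 227).

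Chemokine and cytokine genes rose in 10 of 14 cases, with 11 higher and 1 lower adjusted over the list alone (median 3.37, adjusted p = 0.0018 with an estimated correlation), with Ccl5 at 4.51 ± 0.28 (adjusted p = 1.7e-07). Complement genes rose in 10 of 11 cases, also adjusted over the list alone (median 1.71, adjusted p = 0.0018 with an estimated correlation). Antigen presentation genes did so in 13 of 18, or 15 adjusted over the list alone (median 1.81, adjusted p = 0.0029 with an estimated correlation). Lysosomal genes rose in 18 of 53 cases, or 24 adjusted over the list alone (median 0.43, adjusted p = 0.015 with an estimated correlation). The list of necroptosis, pyroptosis and apoptosis did so in 4 of 12, or 5 adjusted over the list alone (median 0.45, adjusted p = 0.015 with an estimated correlation). Cell cycle genes passed as a list (median 0.79, adjusted p = 0.046 with an estimated correlation) with 1 member called, Cdk1 (2.30 ± 0.51, adjusted p = 0.014), and 3 adjusted over the list alone. The call of Cdk1 ended without PBS replicate 4 or 5 or CBE+GZ-667161 replicate 3 or 4 (adjusted p up to 0.066). Pan-neuronal genes were lower as a list (median -0.30, adjusted p = 0.029 with an estimated correlation), with 0 of 11 genes called by edgeR, DESeq2 or limma-voom, 5 at an unadjusted p under 0.05 and 2 lower adjusted over the list alone. Of 21 cholesterol synthesis genes 0 passed in edgeR, against 2 in DESeq2, 0 in limma-voom and 9 at an unadjusted p under 0.05. Adjusted over the list alone 2 were lower (median -0.33, adjusted p = 0.15 with an estimated correlation), with Hmgcs1 at -0.35 ± 0.15 (adjusted p = 0.30).

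Apoe was higher than in PBS (0.55 ± 0.11, adjusted p = 0.0049), while Gba2 (0.08 ± 0.13, adjusted p = 0.89) and Ugcg (0.01 ± 0.16, adjusted p = 0.99) did not pass. Of the genes lower than in PBS, Krt1, a keratin gene, was the one with the largest fall under the naming rule, from 5.92 ± 0.979 to 1.65 ± 0.489 CPM (-1.87 ± 0.33, adjusted p = 0.0023). Its difference between CBE and PBS was 0.26 ± 0.30 (adjusted p = 0.63). Altogether 435 genes passed, 393 higher and 42 lower, of which 311 and 6 differed by over 2-fold. In 418 of them the 4 and 4 samples did not overlap, as in 9.78% of tested genes against 2.86% by chance. The 6 further lists called by camera with its preset correlation alone had an adjusted p of 0.15 (homeostatic microglia, median 0.78), 0.064 (LXR targets, 0.37), 0.11 (border macrophage and monocyte, 1.53), 0.15 (synapse, -0.22), 0.15 (inhibitory neuron, -0.21) and 0.60 (immediate early genes, -0.47) with an estimated correlation.

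**Figure D3:**
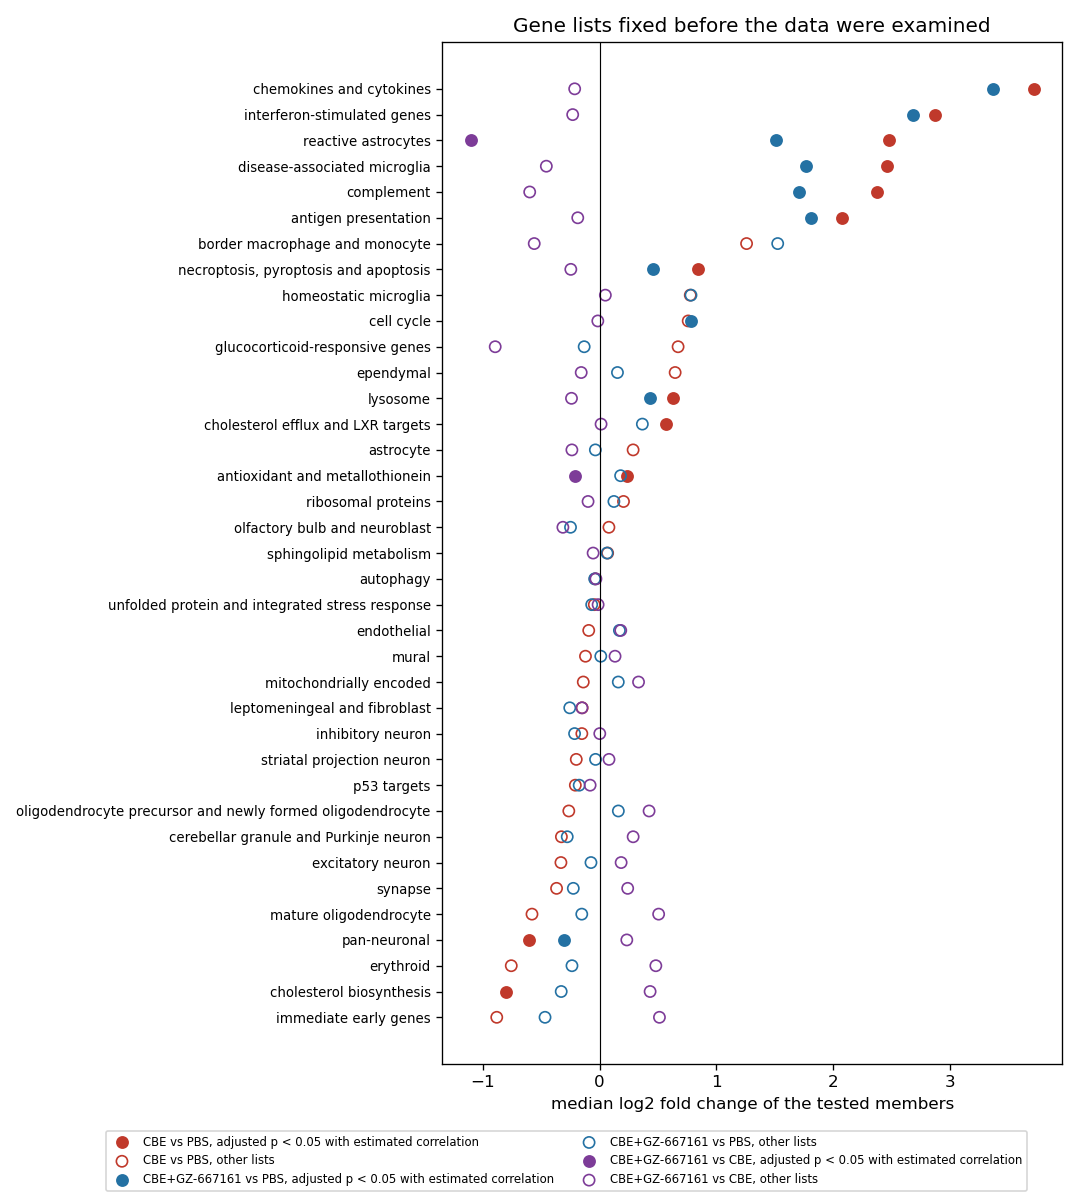
Median log2 fold change (horizontal axis) of the 37 gene lists with at least 5 tested members, with 1 line per list and 1 colour per comparison. Filled points passed camera at an adjusted p under 0.05 with an estimated correlation, which held for 12 lists between CBE and PBS, 10 between CBE+GZ-667161 and PBS and 2 between CBE+GZ-667161 and CBE.

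CBE+GZ-667161 samples were set against CBE samples directly to ask which CBE-associated transcripts the drug altered. Apoc1, an apolipoprotein gene (chromosome 7, 19689481 to 19692660), fell from 37.1 ± 6.08 CPM in CBE to 6.30 ± 0.91 CPM (log2 fold change -2.58 ± 0.20, adjusted p = 7.7e-06). Mt2 (chromosome 8, 94172664 to 94173568) fell from 4897 ± 1246 to 1711 ± 348 CPM (-1.52 ± 0.17, adjusted p = 0.00076), and Apln rose from 7.15 ± 3.02 to 30.6 ± 9.37 CPM (2.19 ± 0.29, adjusted p = 0.0049). Reactive astrocyte genes fell in 11 of 28 cases, or 16 adjusted over the list alone (median -1.10, adjusted p = 0.0075 with an estimated correlation). Among them were Serpina3n at -1.96 ± 0.30 (adjusted p = 0.010), Vim at -1.31 ± 0.21 (adjusted p = 0.010) and Timp1 at -1.79 ± 0.31 (adjusted p = 0.014). Antioxidant and metallothionein genes fell as a list (median -0.21, adjusted p = 0.046 with an estimated correlation), with 2 of 12 called, Mt2 and Mt1, and 3 adjusted over the list alone. Of 39 interferon-stimulated genes 0 passed in edgeR, DESeq2 or limma-voom, and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05 (median -0.23, camera adjusted p = 0.053, and 0.83 with an estimated correlation). The list passed camera at its preset correlation when any of 4 libraries was left out, CBE replicate 4 (median -0.47, adjusted p = 3.2e-09), CBE replicate 6 (-0.27, 0.018), CBE+GZ-667161 replicate 4 (-0.34, 0.0033) or CBE+GZ-667161 replicate 5 (-0.26, 0.031). With an estimated correlation it did not pass in these settings (adjusted p = 0.29, 0.74, 0.66 and 0.80). At the preset correlation it also passed with total counts and no scaling factor (-0.24, 0.045) and with no low-count filter (-0.22, 0.038). In those fits it did not pass with an estimated correlation (adjusted p = 0.82 and 0.77). Cxcl10 differed by 0.11 ± 0.29 (adjusted p = 0.89).

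Of 30 disease-associated microglia genes 5 were lower in CBE+GZ-667161 than in CBE, or 15 adjusted over the list alone (median -0.46, adjusted p = 0.091 with an estimated correlation). The 5 included Lgals3 at -1.89 ± 0.32 (adjusted p = 0.013), Spp1 at -1.30 ± 0.25 (adjusted p = 0.023) and Apoe at -0.65 ± 0.11 (adjusted p = 0.011). Of 15 glucocorticoid-responsive genes 5 were lower, or 9 adjusted over the list alone (median -0.89, adjusted p = 0.095 with an estimated correlation). Among those called were Sgk1 at -1.07 ± 0.17 (adjusted p = 0.010), Lcn2 at -2.92 ± 0.53 (adjusted p = 0.017) and Fkbp5 at -1.78 ± 0.38 (adjusted p = 0.032). Lcn2 and Fkbp5 are also in the reactive astrocyte list. Of 53 lysosomal genes 5 were lower, or 14 adjusted over the list alone (median -0.24, adjusted p = 0.12 with an estimated correlation). Of 11 complement genes 2 were lower, or 7 adjusted over the list alone (median -0.60, adjusted p = 0.18 with an estimated correlation). Of 21 cholesterol synthesis genes 1 passed, Hmgcs1 (0.74 ± 0.15, adjusted p = 0.028), and adjusted over the list alone 9 were higher and 1 lower (median 0.43, adjusted p = 0.18 with an estimated correlation). Of 13 mature oligodendrocyte genes 2 were higher, also adjusted over the list alone (median 0.51, adjusted p = 0.36 with an estimated correlation), Ugt8a (2.19 ± 0.45, adjusted p = 0.029) and Opalin (1.47 ± 0.31, adjusted p = 0.032). Gfap (-1.12 ± 0.25, adjusted p = 0.040) passed, whereas Trem2 (-0.47 ± 0.19, adjusted p = 0.24), Gpnmb (-1.20 ± 0.38, adjusted p = 0.12) and Ugcg (0.28 ± 0.17, adjusted p = 0.42) did not. The preset camera test also called the pan-neuronal (median 0.23), astrocyte (-0.24), synapse (0.24), immediate early (0.51), mitochondrially encoded (0.33), ribosomal protein (-0.10), endothelial (0.18) and erythroid (0.48) lists, with adjusted p = 0.089, 0.11, 0.36, 0.53, 0.12, 0.62, 0.36 and 0.48 with an estimated correlation. Without the day 40 CBE samples the immediate early list had a median of -0.017 and did not pass (adjusted p = 0.54), and with Xist as a covariate the same held for ribosomal protein genes (-0.025, adjusted p = 0.73). With Xist the mature oligodendrocyte (median 0.16, adjusted p = 0.088), synapse (0.21, 0.096) and mitochondrially encoded lists (0.34, 0.063) did not pass either.

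In this comparison 56 genes passed as higher and 105 as lower in CBE+GZ-667161 with edgeR, 12 and 48 of them by over 2-fold. In 148 of these genes the samples did not overlap, as in 8.09% of tested genes against 2.86% by chance. Single libraries decided that count. It was 5 without CBE+GZ-667161 replicate 4, 18 without CBE replicate 4, 28 without CBE+GZ-667161 replicate 3, 31 without CBE replicate 6, 76 without CBE+GZ-667161 replicate 2, 255 without CBE replicate 3 and 269 without CBE+GZ-667161 replicate 5. Of the 43 named genes that passed, 3 kept the call whichever library was left out, Apoc1, Mt2 and Apln. The calls of Serpina3n, Vim, Sgk1, Mt1 and Krt1 ended only without CBE+GZ-667161 replicate 4 (adjusted p from 0.055 to 0.062). The count also followed the day of the CBE samples. Against the 2 day 34 CBE samples 2 genes passed, Apoc1 (-2.36, adjusted p = 0.00019) and Mt2 (-1.19, adjusted p = 0.012), while 1492 had an unadjusted p under 0.05. Against the 2 day 40 CBE samples 777 genes passed, 373 higher and 404 lower. DESeq2 called 478 genes over all 4 CBE samples, and 67 passed in edgeR with Xist as a covariate. By camera at its preset correlation, the interferon-stimulated list was higher in CBE+GZ-667161 than in CBE without the day 34 samples (median 0.31, adjusted p = 0.0092) and lower without the day 40 samples (median -0.66, adjusted p = 1.3e-17). With an estimated correlation neither passed (adjusted p = 0.70 and 0.15).

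Across the 1387 genes called between CBE and PBS, 371 were also higher and 20 also lower in CBE+GZ-667161 than in PBS. In opposite directions 0 were called by edgeR, DESeq2 or limma-voom, with 5 at unadjusted p under 0.05 in both. Independent lists of these sizes would share 27.3 higher and 1.70 lower genes. Both comparisons use the PBS libraries, and 20 simulations of unchanged groups against them gave a median of 0 shared genes in either direction. Another 20 simulations, with the CBE effect but no drug effect, gave medians of 959 (925 to 1023) higher and 586 (552 to 607) lower. The observed overlap was thus below that of a drug without effect, above all for lower genes. With the PBS libraries split between the comparisons, the median over 6 splits was 211 (199 to 227) higher and 1 (0 to 4) lower. Log2 fold changes correlated across genes, which are not independent replicates, at r = 0.777. It was 0.463 in the simulations of unchanged groups, 0.912 in those without a drug effect and 0.556 with split libraries. The covariance was 0.253, against 0.0426, 0.471 and 0.215 in the same order. In the other pair, which shares the CBE libraries, 136 genes called between CBE and PBS moved in the opposite direction between CBE and CBE+GZ-667161, such as Apoc1 and Mt2 downwards and Apln upwards. Of these, 89 went from higher to lower and 47 from lower to higher. The number in the same direction was 0 in edgeR (2 at unadjusted p under 0.05 in both, 0 by DESeq2 or limma-voom). Independent lists would give 9.56 opposite genes and simulations without a drug effect gave a median of 0, while with the CBE libraries split the median was 5 (2 to 121). These simulations drew both groups from the CBE mean, with no difference of day or sex between them. They thus do not show how many shared or opposite genes day or sex would give without a drug effect. The covariance of that pair was -0.172, against -0.0544 in simulations of unchanged groups and -0.123 with split libraries. Its r was -0.643, against -0.557 (-0.575 to -0.536) in simulations of unchanged groups and -0.366 with split libraries. Shared libraries alone thus gave a correlation nearly as strong. In simulations without a drug effect r was -0.235 and the covariance -0.0513. Of the 136 genes, 108 no longer differed from PBS at an adjusted p under 0.05 and 28 still did. Single libraries and the day moved the count of 136. It was 5 without CBE+GZ-667161 replicate 4 and 220 without CBE replicate 3. Without the day 34 CBE samples it was 563, and without the day 40 ones 2.

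The share of the CBE effect that remained with GZ-667161 was estimated as the slope of the fold changes of CBE+GZ-667161 on those of CBE, each against PBS. Over 36 ways of choosing 200 genes on one part of the libraries and taking the slope on the other, the median was 0.763 (0.728 to 0.835). Over the 1387 genes in the libraries they were chosen from, the slope was 0.701, with 0.741 for the genes higher in CBE and 0.299 for those lower. Slopes on genes chosen from the same libraries are biased towards 0. The values by direction were not estimated on other libraries, so 0.299 is not an unbiased share for the lower genes. By the 4 CBE+GZ-667161 samples, the share of the reactive astrocyte change that remained was 0.518, 0.525, 0.504 and 0.779 in replicates 2, 3, 4 and 5, and that of the interferon-stimulated change was 0.773, 0.962, 1.04 and 0.991.

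**Figure D4:**
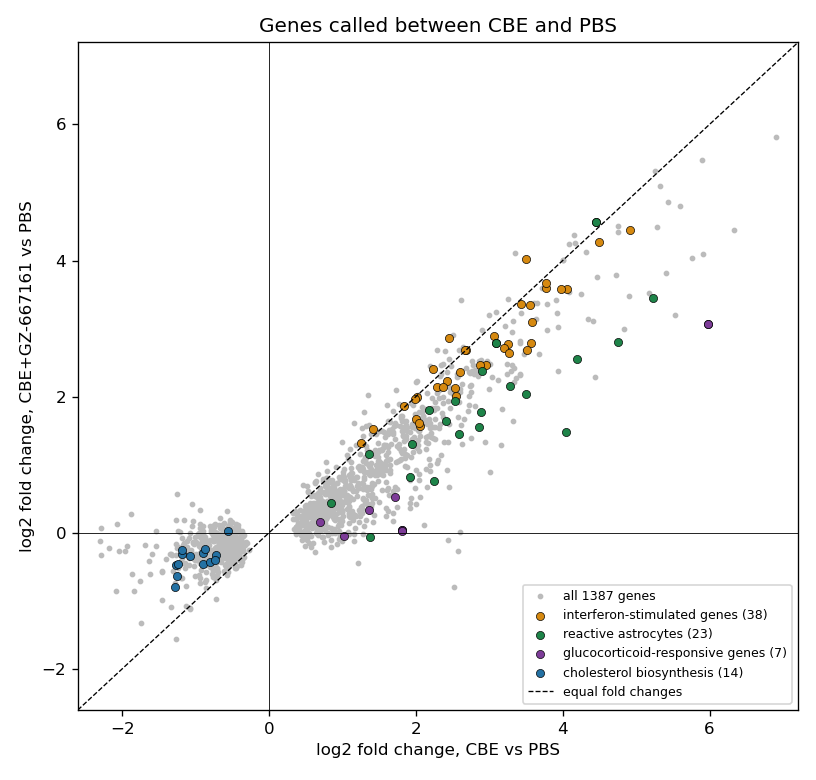
Log2 fold change against PBS of CBE (horizontal axis) and of CBE+GZ-667161 (vertical axis) for the 1387 genes called between CBE and PBS, 1 point per gene, with 4 lists coloured and the dashed line at equal fold changes. The 38 interferon-stimulated genes lie near the line and the 23 reactive astrocyte genes mostly below it; both axes share the PBS libraries.

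The 2 ages within the CBE group were compared because the labels mix them there, with no other group of day 34 to set beside them. Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor (chromosome 17, 28399094 to 28517527), was at 70.6 and 44.4 CPM in the day 34 samples and at 226 and 218 CPM in the day 40 samples (log2 fold change 1.95 ± 0.25, adjusted p = 0.0054), beside 40.2 ± 2.88 CPM in PBS. With it, 3 of 15 glucocorticoid-responsive genes were higher at day 40, or 9 adjusted over the list alone (median 0.84, adjusted p = 0.023 with an estimated correlation). Csf1r (-0.68 ± 0.15, adjusted p = 0.047) and Fcrls (-1.58 ± 0.30, adjusted p = 0.030, named after its value was seen) fell with the homeostatic microglia list, which had 2 of 12 genes lower, or 8 adjusted over the list alone (median -0.98, adjusted p = 0.047 with an estimated correlation). H2-Aa, an MHC class II gene, was at 15.6 and 17.8 CPM at day 34 and at 1.75 and 1.32 CPM at day 40 (-3.42 ± 0.43, adjusted p = 0.0054), and Cxcl10 was lower by -1.33 ± 0.26 (adjusted p = 0.032). Of 39 interferon-stimulated genes 2 were lower at day 40, or 24 adjusted over the list alone (median -0.91, adjusted p = 0.28 with an estimated correlation). Marker lists of regions and other cell types shifted too by camera at its preset correlation, striatal projection neuron genes upwards (median 2.06, adjusted p = 0.0034) and leptomeningeal and fibroblast (-1.77, 2.8e-06) and ependymal genes (-1.23, 0.034) downwards. Their adjusted p with an estimated correlation was 0.56, 0.25 and 0.52. In all 84 genes passed, 33 higher and 51 lower at day 40. That count rests on 2 samples an age. It was 0 in edgeR without CBE replicate 3 or CBE replicate 4, where 1294 and 1425 genes had an unadjusted p under 0.05, 9 without CBE replicate 2, 13 without CBE replicate 6 and 37 without PBS replicate 4. With all samples DESeq2 called 239 genes and limma-voom 16.

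By the values the authors deposited, 1606 genes passed at an adjusted p under 0.05 between CBE and PBS, 539 between CBE+GZ-667161 and PBS and 375 between CBE+GZ-667161 and CBE. Of the genes called here 1328, 424 and 159 were called in the same direction by the authors' deposited values and 0 in the opposite one. Reads of H2-K1 and H2-D1, of Serpina3n and its neighbouring paralogs, of C4b and of Ifit3 and Lilr4b could be split between near-identical genes, and whether counting used the strand was not given in the sources used here. Cxcl10, Irf7, Gfap, Hmgcs1, Mt2, Fkbp5, B2m, Timp1, Ch25h, Cd300lf, Gba2, Csf1r, Srebf1, Sult1a1, Ddc and Il4i1 overlap an annotated gene on the opposite strand, as do Nefl and Nefm with each other, so their counts may include reads of that gene.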

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

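The tests of sex by the ratio of fold changes with and without Xist as a covariate were chosen after the results were seen.

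In 28 of 405 sets of 4 samples 1 sample stood apart from the other 3, where about 20.3 are expected by chance at 1 in 20. The distance is given as the gap to the nearest other sample over the whole range. CBE+GZ-667161 replicate 2 stood apart in 6 genes, low in each, namely Ccl3 (0.851), Bst2 (0.938), Ctss (0.879), Hcar2 (0.927), H2-Q7 (0.859) and Il4i1 (0.895). CBE+GZ-667161 replicate 5 was high for Vim (0.930) and Gfap (0.966) and low in the number of genes with a count (0.877, 15435 genes). CBE+GZ-667161 replicate 4 was apart for Srebf1 (0.844), Stmn2 (0.864) and Gm44214 (0.831), and replicate 3 for Opalin (0.838). Among CBE samples, replicate 6 was high for Timp1 (0.937), replicate 4 low for Slc17a7 (0.942) and replicate 3 high for Hcar2 (0.912). Among PBS samples, replicate 2 was apart for Vim (0.975) and Hmgcs1 (0.858), replicate 3 for Mt2 (0.865), Krt1 (0.867), Agt (0.878) and Cd300lf (1), replicate 4 for Cd68 (0.842), Mmrn2 (0.940), Lilr4b (1) and Hcar2 (1), and replicate 5 for Lgals3 (0.874) and Cxcl13 (1). A value of 1 means that the other 3 samples were equal, here with no count.

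In the test of day 40 against day 34 within CBE, 10 of the reported genes that the naming rule took differed, beside Fcrls, which was named after its value was seen. Higher at day 40 were Ccl17 (log2 fold change 2.85), Ddc (2.20), Fkbp5 (1.95), Sult1a1 (1.52) and Mt1 (1.02), and lower were Cxcl5 (-5.52), Il4i1 (-4.75), H2-Aa (-3.42), Cxcl10 (-1.33) and Csf1r (-0.68). Each of these values rests on 2 samples an age. Of the 23 entries with a date in place of a symbol, 21 had enough counts to be tested in a fit that kept them. Of these, 4 differed between CBE and PBS, with log2 fold changes of -0.49, -0.50, -1.25 and -0.37. Which genes they stand for was not determined.

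In a fit with CBE split by day, 777 genes separated CBE+GZ-667161 from the 2 day 40 CBE samples, but 2 from the 2 day 34 samples. Lower depth of the day 34 libraries is argued against as the whole cause, since with the day 40 CBE libraries thinned to the mean total of the day 34 CBE libraries, in 10 thinnings, a median of 628 (601 to 671) genes still passed. Collection day and stage of disease cannot be told apart, because 0 samples of the other groups were of day 34. Either may lie behind the difference, as may other differences between these samples that were not tested. Marker lists of regions and other cell types also shifted between the days at the preset correlation, but not with an estimated one. The biological explanation stays a hypothesis.

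All 4 CBE samples had Y-linked counts and almost no Xist, while 2 PBS and 3 CBE+GZ-667161 samples had Xist, so sex could contribute to the differences. For the called genes, the median ratio of fold changes with Xist as a covariate to those without was 0.997 (quartiles 0.933 to 1.08) for CBE against PBS. For CBE+GZ-667161 against CBE it was 1.04 (0.924 to 1.16). These ratios argue against sex as the whole cause, if its effect was alike in all groups. As no CBE sample had the Xist pattern, the fit could not estimate or remove an effect of sex particular to CBE. In the second comparison the count of genes fell from 56 higher and 105 lower to 67 in all as the median standard error rose from 0.183 to 0.234, while the median size of the log2 fold change went from 0.86 to 0.91 and every called gene kept its sign. In CBE+GZ-667161 only replicate 4 had the Y-linked pattern of the CBE samples, and without it 5 genes passed in the second comparison. An effect of sex particular to CBE and a part played by sex in single genes stay open.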

How the results depend on the processing

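The alternatives without the day 40 CBE samples, the weighted slope, Xist as a covariate for lists and opposite directions, and an estimated correlation within other alternatives were chosen after the results were seen; the cause of a change was not tested unless named.

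Genes called between CBE and PBS (1387) ran from 962 without CBE replicate 6 to 1515 without CBE replicate 3, and were 676 at an adjusted p under 0.01, 805 with glmTreat and 751 without the day 40 CBE samples. Those between CBE+GZ-667161 and PBS (435) ran from 326 to 448 with 1 library left out and were 261 at an adjusted p under 0.01. Those between CBE+GZ-667161 and CBE (56 higher and 105 lower) ran in all from 5 without CBE+GZ-667161 replicate 4 to 269 without CBE+GZ-667161 replicate 5. They were 478 with DESeq2, 31 in a fit of the 2 groups, 6 at an adjusted p under 0.01, 21 with glmTreat, 692 without the day 34 CBE samples, 777 with day as a covariate, 67 with Xist and 2 without the day 40 CBE samples. Only the CBE group held 2 days, so the fit with day as a covariate compared CBE+GZ-667161 with the day 40 CBE samples. The stricter thresholds lower counts by construction. The share of higher genes was 34.8%, 47.5% without day 34 and 55.2% with Xist.

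Genes that moved in opposite directions (136) ran from 5 without CBE+GZ-667161 replicate 4 to 220 without CBE replicate 3, and were 354 with DESeq2, 563 without the day 34 samples, 2 without the day 40 samples and 57 with Xist. Leaving out CBE replicate 4 gave 17, CBE replicate 6 gave 30, CBE+GZ-667161 replicate 2 gave 64, replicate 3 gave 26 and replicate 5 gave 216. Genes between the days (84) ran from 0 without CBE replicate 3 or 4 (edgeR) to 104 without CBE+GZ-667161 replicate 2, with 239 by DESeq2, 16 by limma-voom and 165 in the 4 CBE samples alone. Called lists, 24, 17 and 16 in the order of the comparisons, were 12, 10 and 2 with an estimated correlation and 20, 16 and 10 with fry, and ran from 22 to 24, 17 to 19 and 16 to 23 with 1 library left out. The remaining share (0.763) was 0.647 without the day 34 samples and ran from 0.720 without CBE+GZ-667161 replicate 5 to 0.814 without CBE+GZ-667161 replicate 2. Other scaling factors and low-count filters kept each of these counts within 1.5 times.

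In CBE+GZ-667161 against CBE, directions turned for interferon-stimulated genes (median 0.31 without day 34, against -0.23 with all samples and -0.66 without day 40), homeostatic microglia (-0.41 without day 40) and leptomeningeal genes (0.70 without day 34). These are calls at the preset correlation, and with an estimated one the adjusted p was 0.70, 0.16 and 0.60 (interferon-stimulated without day 40, 0.15). H2-Aa between CBE and PBS was -2.05 without day 34 and -2.04 with day as a covariate, and both fits set the day 40 CBE samples against PBS. Over named genes and alternatives, 11182 results passed in the same direction as in the main fit, or passed in neither fit, whatever their direction. A further 797 no longer passed, 135 newly passed and 2 turned with a call in either fit.

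Replicate numbers did not pair the samples: of 10 same-number pairs 1 had a correlation of deviations over 0.1 (-0.0783 to 0.240), and 3 of 12 samples correlated best with their own number. With replicate number as a block, 947, 404 and 82 genes were called and 76 moved in opposite directions. The interferon-stimulated list then passed between CBE+GZ-667161 and CBE at the preset correlation (median -0.27, adjusted p = 0.0093), but not with an estimated one (0.74). Small changes were often missed in simulation, with 17.9%, 19.4% and 19.4% of 1.5-fold changes called, and how far depth, the spread between samples or their number limits this was not tested.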

Other observations

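The test of the cholesterol genes was chosen after the result was seen.

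Of the genes of vessels, Flt1 and Mmrn2 were lower in CBE and higher again with GZ-667161. Flt1, a VEGF receptor gene of endothelium, was at 69.2 ± 7.01 CPM in PBS, 48.0 ± 8.32 in CBE and 78.9 ± 5.69 in CBE+GZ-667161 samples (n = 4 each), with log2 fold changes of -0.53 ± 0.14 (edgeR adjusted p = 0.019) for CBE against PBS and 0.72 ± 0.14 (adjusted p = 0.023) for CBE+GZ-667161 against CBE. Mmrn2, an endothelial matrix gene, changed by -1.25 ± 0.36 (adjusted p = 0.036) and 1.82 ± 0.36 (adjusted p = 0.025). Of 12 endothelial genes 1 rose and 1 fell between CBE and PBS, with 1 and 2 adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.52). Between CBE+GZ-667161 and CBE 1 of 12 was higher, or 4 adjusted over the list alone, and the list call was lost with an estimated correlation (adjusted p = 0.36). Several single libraries decided these calls. Between CBE and PBS that of Flt1 ended without any of 3 libraries (PBS replicates 2 and 5 and CBE replicate 6, adjusted p up to 0.082). That of Mmrn2 ended without any of 8 (PBS replicates 2, 3 and 5, CBE replicates 2, 4 and 6 and CBE+GZ-667161 replicates 3 and 4, adjusted p up to 0.12). Between CBE+GZ-667161 and CBE both ended without CBE replicate 6 or CBE+GZ-667161 replicate 3 or 4 (adjusted p up to 0.085 and 0.089), and that of Mmrn2 also without CBE replicate 4. When CBE+GZ-667161 was set against the day 34 CBE samples alone, neither gene passed. Without the day 40 CBE samples the endothelial list did not pass camera at its preset correlation either (median 0.076, adjusted p = 0.14).

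Some astrocyte genes other than reactive markers were lower with GZ-667161 than with CBE alone. Of a list of 13, 4 were lower, also when adjusted over the list alone (median -0.24), and the list call was lost with an estimated correlation (adjusted p = 0.11). Slc1a3, a glutamate transporter gene, was at 300 ± 4.53, 476 ± 33.0 and 332 ± 37.1 CPM in PBS, CBE and CBE+GZ-667161 samples (n = 4 each), with 0.67 ± 0.10 (edgeR adjusted p = 0.00026) for CBE against PBS and -0.52 ± 0.10 (adjusted p = 0.024) for CBE+GZ-667161 against CBE. Gjb6, a gap junction gene, fell by 0.91 ± 0.19 on the log2 scale (adjusted p = 0.032) and Etnppl, a phospholyase gene of astrocytes outside the list, by 3.32 ± 0.58 (adjusted p = 0.014) in that comparison. These calls ended without CBE+GZ-667161 replicate 4, with adjusted p of 0.085, 0.12 and 0.071. They ended too without CBE replicate 4 or CBE replicate 6, and those of Slc1a3 and Gjb6 without CBE+GZ-667161 replicate 2 or 3. When CBE+GZ-667161 was set against the day 34 CBE samples alone, none of these genes passed.

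Other splits of the 8 samples of each comparison into 4 and 4 were counted, 35 in each. For the gene counts 1 of 35, the real one, gave as many genes. It gave 1387 against at most 1 for CBE and PBS, and 435 against at most 4 for CBE+GZ-667161 and PBS. For CBE+GZ-667161 and CBE it gave 56 higher and 105 lower against at most 1. A share of 1 in 35 is the smallest these splits can give, so chance is argued against but not excluded. The other splits mix the groups, which widens the spread within them. The last count also hung on single libraries and on the day of the CBE samples. For the count of lists 1 of 35 splits was as large for CBE and PBS (24, highest other 23), a margin of 1 list, but 9 of 35 were for CBE+GZ-667161 and PBS (17, highest other 22) and 5 of 35 for CBE+GZ-667161 and CBE (16, highest other 22), so chance cannot be excluded for those counts of lists. Other splits called a median of 10.5, 8.5 and 11 lists. Of 70 ways to name 4 of the 8 CBE and CBE+GZ-667161 samples CBE, 1 gave as many genes in opposite directions (136, highest other 2) and 1 as low a slope over called genes (0.701, lowest other 0.777).

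Cholesterol synthesis genes were lower in CBE (median log2 fold change -0.80, quartiles -1.19 to -0.36). Fewer oligodendrocytes may account for it, and cannot be told apart from a change within cells, as the median of the mature oligodendrocyte genes, -0.58, lay within the quartiles of the cholesterol genes. Dilution by RNA from other cells was not tested and stays open.

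A hypothesis was that GZ-667161 acts differently on reactive astrocyte and interferon-stimulated genes. The mean share of the CBE change that remained was 0.581 for the first and 0.942 for the second list, a difference of 0.361, with a two-sided exact permutation p of 0.143 over 70 assignments. The hypothesis was not borne out at 0.05, but a p that misses the threshold excludes nothing. The CBE samples of the 2 days spread the interferon share from 0.684 to 1.25, against 0.973 to 1.05 for the astrocyte share, so a difference stays possible.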
